A study of Mus musculus with 9 samples.

How the data were processed

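The table used gives FPKM for 34669 genes, named by Ensembl identifiers, in 9 libraries, 3 from each of the sham, vehicle-treated and TJ0113-treated groups. RNA was taken from the renal cortex with TRIzol, and 1 µg went into paired-end messenger RNA libraries made with an Abclonal kit. The submitters' notes name HISAT2 for alignment, without a version; the counting tool, the genome build and the annotation are not given in the sources used here. The treatment labels of the samples write the compound as TJ013 and the series text as TJ0113, and both were read as the same compound. The FPKM values were made by the authors before deposit, as fragments scaled by gene length and by the fragments counted in each library, with no further normalization between libraries that the values show, and were used as deposited. They were read as FPKM because they are not whole, their sums differ between libraries (330815.1 to 405810.2), and low values multiplied by gene length fall on equal steps within a library. Of the values below 20 reads, 98.7 to 98.9 percent lay within 0.02 of a whole step or of the middle between steps. Gene symbols were taken from GENCODE release M21, which names 33893 of the identifiers (97.8 percent); the other 776 kept their identifiers.

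Replicate libraries were compared for copies. The median squared difference between replicates, in units of counting noise, was 2.9 to 3.1 in sham, 18.2 to 56.3 in the vehicle group and 8.9 to 20.5 in the TJ0113 group, against 0.455 for counting noise alone, so no library repeats another. The median SD of a gene on the log2 scale was 0.09 in sham, 0.27 in the vehicle group and 0.19 in the TJ0113 group. The first principal component held 75.5 percent of the variance and placed vehicle library 2 at -8, between the sham libraries (-61.7 to -52.5) and vehicle libraries 1 and 3 (30.8 and 70.6). Replicate numbers were not treated as pairs, and a fit with the replicate number as a block is given in the closing part. After removal of group means, vehicle and TJ0113 libraries of the same number correlated at -0.06, 0.50 and 0.56. TJ0113 library 2 with vehicle library 3, and TJ0113 library 3 with vehicle library 2, were at -0.54. TJ0113 and sham libraries of the same number were at -0.15, 0.03 and 0.03.

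Differences between groups were tested with limma on log2(FPKM + 1) in 1 fit of all 9 libraries, with a variance trend, for the 15453 genes with a mean of at least 0.5 FPKM, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. FPKM were not rescaled between libraries. The SE of a log2 change comes from this fit, and the SD beside FPKM is that of 3 libraries. The groups, the tests, the gene lists, the rule by which genes are named and 15 alternative settings were chosen before the data were examined. That rule names the 8 largest changes each way among genes that pass and whose groups do not overlap. It also names up to 4 members of each called list by smallest p, whether or not they pass or overlap. Some genes, such as Havcr1 and Gpx4, were fixed beforehand. Nr4a1, Egr1, Egr2 and Fosb between TJ0113 and vehicle, and the further genes in the closing part, were picked after their values were seen. Some genes that meet the rule are not reported here, and they stay in the tests and lists.

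Of 52 gene lists with 989 members in all, 988 members were found, and 49 lists had at least 5 tested members. Neutrophil markers (3 members tested), adrenal genes (2) and skeletal muscle genes (2) were too short to test. Lists were tested with camera at a preset correlation of 0.01 between genes, which asks whether a list moved relative to other genes, with Benjamini-Hochberg adjustment over the 49 lists of a comparison. Camera with a correlation estimated from the data and fry, which asks whether a list moved at all, were run beside it.

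Recovery was tried on simulated libraries with known changes, drawn with the spread of these data and with errors that are independent between genes. Changes of 2-fold were recovered in 70 percent of genes between vehicle and sham and 72 percent between TJ0113 and vehicle. Changes of 4-fold were recovered in 99 and 100 percent. Of the calls, 12 of 181 and 41 of 213 were false, both larger shares than the threshold for adjusted p-values, the second by far. These rates hold for the simulated libraries only and do not give the power of the real comparisons. Large differences of Fos and Atf3 between TJ0113 and vehicle did not pass in the real libraries. Correlations between comparisons that share libraries were set beside 1000 simulated draws of unchanged groups. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.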

Results

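Messenger RNA was measured in the renal cortex of male C57BL/6 mice, 10 weeks old. The injured groups were taken on day 14 after surgery, and no day is recorded here for the sham mice. The 9 libraries fell into 3 groups of 3. Mice of the injured groups had both renal pedicles clamped for 30 min, a bilateral ischemia-reperfusion injury (bIRI) that damages mainly the tubules, and were given either vehicle or the compound TJ0113 by daily gavage, from 3 days before surgery until sacrifice. Sham mice had the same operation without clamping. Whether they were gavaged is not given in the sources used here, so gavage cannot be told apart from clamping in differences from sham. Such differences are called injury below with that limit. The series title places the work in the passage from acute injury to chronic kidney disease and names ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation, and the mitochondria of the tubules. Limma's p-values below reflect only the spread between these samples. Those of camera at the preset correlation set a list against other genes and do not measure the spread between mice.

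The first comparison, vehicle-treated bIRI against sham, addressed what the injury left in the cortex after 14 days. Genes of tubular damage, scarring and inflammation were far higher, and transporters and enzymes of the healthy proximal tubule were lower. Havcr1, which encodes the injury marker KIM-1, had 1.61 ± 0.249 FPKM in sham and 238 ± 107 FPKM in the vehicle group (SD, n = 3). Col1a1, a chain of type I collagen, went from 1.82 ± 0.219 to 56.5 ± 39.6 FPKM (SD, n = 3). Lrp2, the endocytic receptor megalin of the proximal tubule, went from 163 ± 32.7 to 55.1 ± 20 FPKM (SD, n = 3). The median of all genes was 0.30 higher on the log2 scale in the vehicle group than in sham, and log2 changes from sham are given below relative to the median gene of their comparison.

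The largest rises after Havcr1 (6.10 ± 0.49, SE) were those of the complement component C3 (5.22 ± 0.48), the lysozyme gene Lyz2 (4.83 ± 0.58), the chemokine Cxcl1 (4.63 ± 0.75), and Lcn2, which encodes the injury marker NGAL (4.56 ± 0.56). Aoc1 (4.44 ± 0.38), the keratin Krt20 (4.29 ± 0.50) and Serpina10 (4.23 ± 0.45) followed. The largest falls were those of the organic anion transporter Slco1a1 (-3.98 ± 0.97), Akr1c18 (-3.63 ± 0.87), Cyp4a12a (-3.58 ± 0.29), Azgp1 (-3.34 ± 0.69), Pzp (-3.20 ± 0.75), Dnase1 (-3.19 ± 0.44), Cyp2d12 (-3.16 ± 0.58) and Aadat (-2.97 ± 0.66). Across these 16 genes, limma's Benjamini-Hochberg adjusted p ran from 0.00149 for Havcr1, C3, Aoc1 and Cyp4a12a to 0.0219 for Slco1a1. Cyp4a12a has a close paralog, Cyp4a12b, with which it can share reads.

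**Figure D1:**
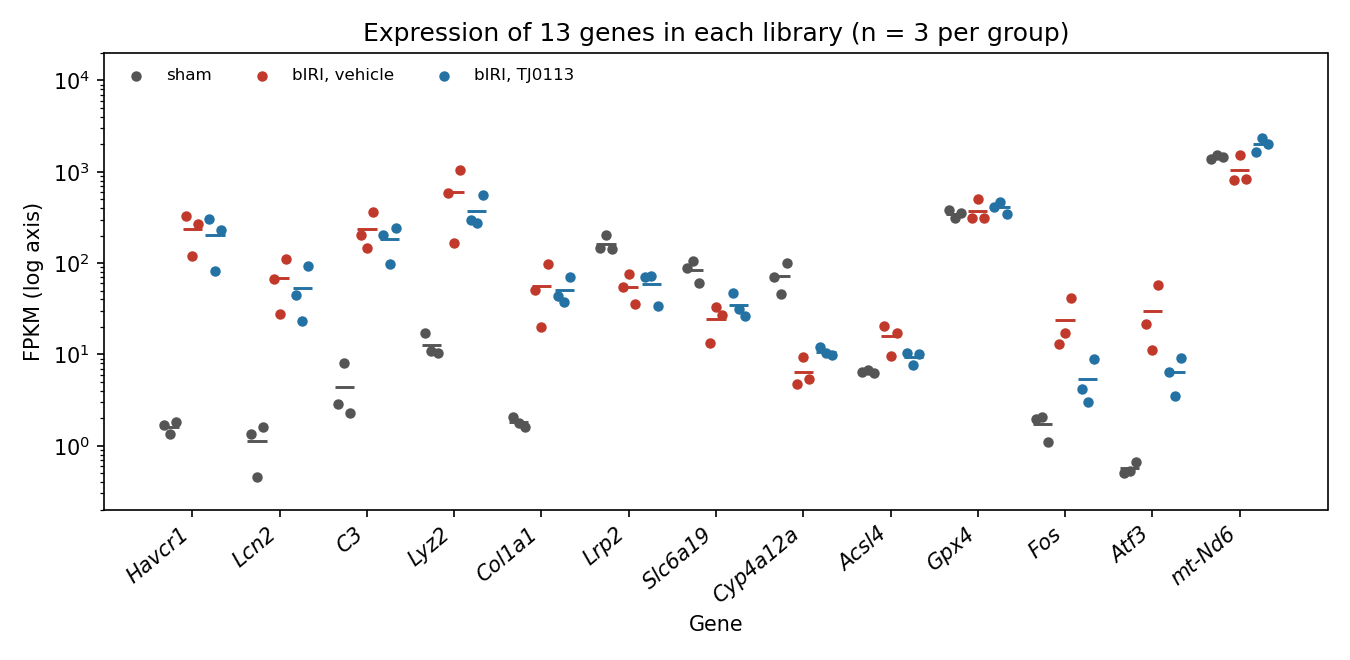
FPKM of 13 genes in each library on a log axis, with 3 points per group and a bar at the group mean. Havcr1 lies at a mean of 1.61 FPKM in sham, 238 FPKM in vehicle-treated bIRI and 205 FPKM in TJ0113-treated bIRI, and Fos at 1.71, 23.8 and 5.39 FPKM.

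Scar and injury genes rose nearly as whole groups. All 32 extracellular matrix and myofibroblast genes tested rose, with a median of 2.12 relative to the median gene; Col3a1 rose by 3.72 ± 0.48, Timp1 by 3.81 ± 0.54 and Col15a1 by 2.67 ± 0.40. Of 27 tubular injury and failed repair genes 26 rose (median 2.11), among them Vcam1 (3.90 ± 0.38). Camera with Benjamini-Hochberg adjustment gave these lists adjusted p = 5.72e-10 and 8.20e-09; both had adjusted p = 0.554 with an estimated correlation. Fibroblast and pericyte markers rose in 8 of 12 members (9 adjusted over the list alone; 6 with median-ratio scaling and 2 with quantile normalization), with Thy1 at 2.19 ± 0.35 and Pdgfrb at 1.18 ± 0.36; camera's Benjamini-Hochberg adjusted p was 0.0486, and 0.569 with an estimated correlation. That call was lost in many settings, among them equal FPKM sums (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0686), a mean of at least 2 FPKM (0.0795), and the fits without sham library 3 (0.0699), vehicle library 1 (0.0661), vehicle library 3 (0.0667), TJ0113 library 2 (0.0546) or TJ0113 library 3 (0.0666).

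Immune genes rose alongside. Of 26 cytokine, chemokine and NF-kB genes 24 rose, with the monocyte chemoattractant Ccl2 at 4.22 ± 0.47 and the adhesion molecule Icam1 at 2.04 ± 0.34. Of 19 macrophage markers 18 rose (19 adjusted over the list alone), including Cd14 (3.36 ± 0.44) and the galectin Lgals3 (2.23 ± 0.37). MHC class II and dendritic cell genes rose in 9 of 10 members (10 adjusted over the list alone), with the invariant chain Cd74 at 2.73 ± 0.40. Complement genes rose in 14 of 16 members, with C1qa at 3.39 ± 0.55, and 1 fell. T and NK cell markers rose in 9 of 13 members (11 adjusted over the list alone), with Ccl5 at 2.05 ± 0.27, and interferon-stimulated genes in 22 of 27 (23 adjusted over the list alone), with Gbp2 at 1.29 ± 0.24. Fewer members of these last lists rose with median-ratio scaling (5 of the T and NK cell and 17 of the interferon list) and with quantile normalization (3 and 13). Camera with Benjamini-Hochberg adjustment called all 6 lists, with adjusted p from 6.81e-08 for the cytokine list to 0.0114 for the T and NK cell list. With an estimated correlation the adjusted p was 0.554 for the cytokine, macrophage, MHC class II and complement lists and 0.569 for the T and NK cell and interferon lists.

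Proliferation and stress genes were also higher. Cell cycle genes rose in 22 of 23 members (23 adjusted over the list alone), including Mki67 (1.19 ± 0.24) and Rrm2 (0.94 ± 0.15). All 14 immediate early genes, transcription factors and regulators that are induced within minutes of a stimulus, rose with a median of 1.92, led by Atf3 (3.71 ± 0.50), Fos (2.75 ± 0.43), Egr2 (2.26 ± 0.41) and Btg2 (2.25 ± 0.38). Of 19 p53 targets and senescence genes 13 rose (adjusted over the list alone 16 rose and 1 fell), with Gdf15 at 3.21 ± 0.49 and Phlda3 at 1.82 ± 0.34. Of 40 cytosolic ribosomal protein genes 32 rose (36 adjusted over the list alone; 15 with median-ratio scaling and 27 with quantile normalization), with Rps20 at 1.22 ± 0.26. Camera's Benjamini-Hochberg adjusted p was 1.55e-06 for the cell cycle, 2.00e-05 for the immediate early, 0.00194 for the p53 and 1.19e-05 for the ribosomal list; with an estimated correlation it was 0.554 for the first 3 and 0.569 for the ribosomal list.

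Proximal tubule markers were lower. Of 31 tested, 14 fell (23 adjusted over the list alone) and 30 had a negative change, with a median of -1.34; the neutral amino acid transporter Slc6a19 was at -2.10 ± 0.35, Acsm1 at -1.99 ± 0.29, Lrp2 at -1.89 ± 0.34 and Gatm at -1.69 ± 0.34. Male-biased kidney genes, which need androgen for full expression, fell in 6 of 10 members (8 fell adjusted over the list alone, and 1 rose), with Odc1 at -2.32 ± 0.42 and Cyp2j13 at -1.46 ± 0.33. All 21 enzymes of the tricarboxylic acid cycle had a negative change and 4 fell (0 adjusted over the list alone; 1 with equal FPKM sums and 7 with median-ratio scaling), with Suclg1 at -1.25 ± 0.31 and Pdha1 at -1.07 ± 0.24. Of 28 fatty acid oxidation genes 2 fell (0 adjusted over the list alone; 1 with equal FPKM sums, where 1 rose, and 4 with median-ratio scaling), the fatty acid transporter Cd36 (-2.37 ± 0.57) and Etfdh (-1.05 ± 0.26). Camera with Benjamini-Hochberg adjustment gave these 4 lists adjusted p = 8.49e-18, 5.99e-08, 5.72e-10 and 1.20e-06, and 0.554 for each with an estimated correlation. Vehicle library 3 stood apart in the male-biased list, whose mean was -4.12 there against -1.84 and -1.14 in vehicle libraries 1 and 2. Camera with Benjamini-Hochberg adjustment also called thick ascending limb (median -0.64, adjusted p = 0.0134), distal convoluted and connecting tubule (-0.72, 0.0174), intercalated cell (-0.48, 0.0189) and endothelial markers (-0.42, 0.0179) downward. With an estimated correlation none was called. The endothelial call was lost without vehicle library 2 or sham library 1, and the others without vehicle library 3. With quantile normalization each was lost (camera, Benjamini-Hochberg adjusted p = 0.547, 0.353, 0.263 and 0.0774 in the order above). All but the endothelial call were also lost with median-ratio scaling (camera, Benjamini-Hochberg adjusted p = 0.119, 0.125 and 0.0972).

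Mitochondrial transcripts lay below the median gene. Of the 13 messenger RNAs encoded by mitochondrial DNA 12 had a negative change (median -1.22 relative to the median gene) and mt-Atp8 (-2.38 ± 0.50) passed, with camera's Benjamini-Hochberg adjusted p = 5.97e-06 for the list and 0.554 with an estimated correlation. All mitochondrially encoded genes together, transfer RNAs included, held 25.51, 27.71 and 27.02 percent of FPKM in the sham libraries, against 18.6, 23.31 and 12.12 percent in the vehicle libraries. Nuclear-encoded complex I subunits had a median of -0.41 relative to the median gene (camera with Benjamini-Hochberg adjustment, adjusted p = 5.15e-05; 0.569 with an estimated correlation), with 2 of 36 lower and 1 higher past limma's threshold (0 adjusted over the list alone). With quantile normalization both lists lost their calls, at -0.36 for the mitochondrial messenger RNAs and -0.12 for complex I (camera with Benjamini-Hochberg adjustment, adjusted p = 0.31 and 0.201). As fitted, the complex I median was -0.11, and 0.05 once all libraries were scaled to equal FPKM sums. Of 22 mitochondrial dynamics and biogenesis genes 2 rose and 3 fell, against 3 and 1 with equal FPKM sums and 0 and 9 with median-ratio scaling. The mitochondrial sirtuin Sirt3 fell, at -1.11 ± 0.18 relative to the median gene (limma, Benjamini-Hochberg adjusted p = 0.014), and so did Ppargc1a, a coactivator of mitochondrial biogenesis, at -0.76 ± 0.14 (adjusted p = 0.0311; 0.11 with equal FPKM sums).

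Genes tied to ferroptosis moved both ways, and the direction of those of mitophagy, the removal of damaged mitochondria, depended on scaling. Among 22 ferroptosis drivers 8 rose and 1 fell, and among 25 suppressors 7 rose and 4 fell, with camera's Benjamini-Hochberg adjusted p = 0.86 and 0.144. The driver list had a median of -0.16 relative to the median gene, a median of 0.14 as fitted (-0.12 with median-ratio scaling, -0.15 with quantile normalization) and a mean of 0.51 as fitted, so these differ in sign. Fry, which compares a list with no change and not with other genes, called both lists upward, with limma's Benjamini-Hochberg adjusted p = 0.0192 for drivers and 0.0413 for suppressors. Acsl4, which supplies the polyunsaturated lipids that are peroxidised, rose from 6.44 ± 0.225 to 15.8 ± 5.56 FPKM (SD, n = 3; 0.82 ± 0.24 relative to the median gene; limma, Benjamini-Hochberg adjusted p = 0.0129). Gpx4, the peroxidase that detoxifies lipid peroxides, was at 348 ± 37.4 and 375 ± 112 FPKM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.819). The cystine transporter Slc7a11 lay below the expression filter, at 0.016 FPKM in sham and 0.188 FPKM in the vehicle group. Of 32 mitophagy genes 4 rose and 2 fell in the values as deposited, against 8 and 1 with equal FPKM sums, 0 and 4 with median-ratio scaling and 0 and 3 with quantile normalization (camera as deposited, Benjamini-Hochberg adjusted p = 0.0898); Pink1 had a Benjamini-Hochberg adjusted p of 0.215 by limma.

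In total 5676 of 15453 genes changed between vehicle-treated bIRI and sham, 4839 higher and 837 lower (limma, adjusted by Benjamini-Hochberg), and 1783 of them changed by at least 1 on the log2 scale as fitted. The groups did not overlap in 56.8 percent of genes, where chance gives 10 percent. The balance of directions depended on scaling, with 85.3 percent of the called genes higher in the values as deposited, 91 percent with equal FPKM sums, 58.3 percent (2725 higher, 1949 lower) with median-ratio scaling, 46.8 percent (2041 higher, 2320 lower) with quantile normalization and 53.2 percent with the length trend removed. The count fell to 862 without sham library 2, 1022 without sham library 3, 2661 without sham library 1, 2565 without vehicle library 3 and 3198 without vehicle library 1, and was 8789 without vehicle library 2. Camera called 33 of the 49 lists tested, 15 upward and 18 downward, against 0 with an estimated correlation and 25 with fry.

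**Figure D2:**
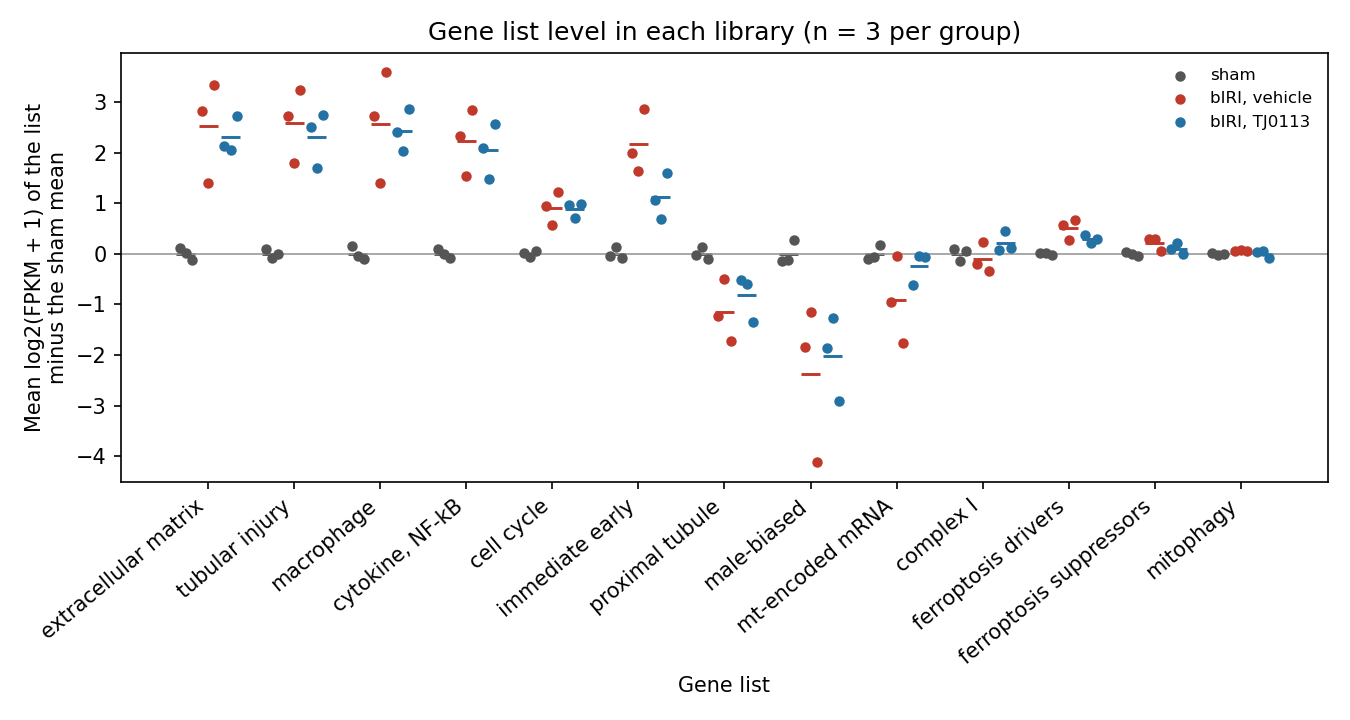
Mean log2(FPKM + 1) of 13 gene lists in each library, minus the sham mean, with 3 points per group and a bar at the group mean. Extracellular matrix genes average 2.53 in the vehicle group and 2.30 in the TJ0113 group, and immediate early genes 2.17 and 1.12.

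The second comparison, TJ0113 against vehicle among injured mice, addressed the effect of the compound. No gene passed the test, injury and scar genes included. Havcr1 was at 205 ± 114 FPKM with TJ0113 and 238 ± 107 with vehicle, Lcn2 at 54 ± 36.1 and 68.4 ± 41.8, and Col1a1 at 50.5 ± 17.6 and 56.5 ± 39.6 (SD, n = 3). Among the lists that camera called, immediate early genes had the largest median difference in the values as deposited (without vehicle library 2 the mitochondrial messenger RNAs had a larger one, 1.12 against -1.02), with Fos at 5.39 ± 3.11 FPKM against 23.8 ± 15.1 and Atf3 at 6.37 ± 2.85 against 30 ± 24.4 (SD, n = 3). The median of all genes differed by -0.03, and changes of single genes between these 2 groups are given as fitted.

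All 14 immediate early genes were lower with TJ0113, with a median of -0.94 relative to the median gene (camera with Benjamini-Hochberg adjustment, adjusted p = 2.32e-10; 0.964 with an estimated correlation). None passed limma over all genes, and 8 passed adjusted over the list alone. Those 8 were Fos (-1.90 ± 0.43), Atf3 (-1.85 ± 0.50), Egr1 (-1.45 ± 0.47), Btg2 (-1.42 ± 0.38), Nr4a1 (-1.39 ± 0.46), Egr2 (-1.10 ± 0.41), the phosphatase gene Dusp1 (-1.04 ± 0.31) and Fosb (-0.92 ± 0.28). The mean of the list, relative to sham, lay between 1.64 and 2.87 in the vehicle libraries and between 0.69 and 1.61 in the TJ0113 libraries. The list kept its direction and its camera call in each of the 6 fits that left out 1 injured library. The p53 and senescence list was lower as well, with 15 of 19 members negative and a median of -0.29 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0048; 0.964 with an estimated correlation; 0.0874 without TJ0113 library 2; 0.0504 with the proximal tubule level as a covariate). Its smallest p-values belonged to Btg2, Aen (-0.44 ± 0.12), Trp53inp1 (-0.49 ± 0.21) and Zmat3 (-0.26 ± 0.11), and 0 members passed adjusted over the list alone.

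Most subunits of complexes I and IV and of ATP synthase were higher with TJ0113, while the list of complexes II and III was not called (median 0.18; camera, Benjamini-Hochberg adjusted p = 0.0804). Of 36 nuclear-encoded complex I subunits 33 were higher, with a median of 0.34 relative to the median gene, among them Ndufa12 (0.98 ± 0.34), Ndufa3 (0.67 ± 0.20), Ndufa5 (0.61 ± 0.17) and Ndufa13 (0.59 ± 0.23). Complex IV subunits were higher in 11 of 12 members (median 0.30), with Cox6b1 at 0.46 ± 0.23, and ATP synthase subunits in 12 of 15 (median 0.19), with Atp5k at 0.58 ± 0.25. Lower ATP synthase subunits included Atp5a1, at 473, 637 and 295 FPKM in TJ0113 libraries 1 to 3 against 504, 633 and 373 with vehicle. Atp5b was at 424, 591 and 258 FPKM against 479, 588 and 330. The complex I subunit Ndufs1 was lower as well, at 20.3, 23.3 and 15.3 FPKM against 24.5, 26.7 and 14.5. The messenger RNAs encoded by mitochondrial DNA were higher in 11 of 13 members (median 0.70), with mt-Nd3 at 1.64 ± 0.64 and mt-Nd6 at 0.97 ± 0.32. Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.24e-11 for complex I, 0.00125 for complex IV, 0.00401 for ATP synthase and 5.93e-04 for the mitochondrial messenger RNAs, and 0.964 for each with an estimated correlation. With the length trend removed the adjusted p by camera with Benjamini-Hochberg was 0.0964 for both complex IV and ATP synthase, and with the proximal tubule level as a covariate 0.328, 0.825 and, for the mitochondrial messenger RNAs, 0.0925. With quantile normalization the median of the mitochondrial messenger RNAs was 0.17 as fitted, against 0.67, and ATP synthase lost its call (camera, Benjamini-Hochberg adjusted p = 0.114). No member of the 4 lists passed limma, over all genes or adjusted over the list alone. All mitochondrially encoded genes together, transfer RNAs included, held 19.25, 24.26 and 25.52 percent of FPKM in the TJ0113 libraries.

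Proximal tubule markers moved with the respiratory subunits, higher in 28 of 31 members with a median of 0.39 (camera with Benjamini-Hochberg adjustment, adjusted p = 2.58e-04; 0.964 with an estimated correlation). Slc22a8 was higher by 0.87 ± 0.37, Miox by 0.77 ± 0.40 and the sulfate transporter Slc13a1 by 0.61 ± 0.17, and 0 members passed adjusted over the list alone. Markers of 3 other segments leaned the other way without a call, lower in 10 of 10 thick ascending limb, 9 of 9 principal cell and 9 of 10 intercalated cell markers (camera, Benjamini-Hochberg adjusted p = 0.299, 0.11 and 0.569), with TJ0113 library 1 lowest at -1.56, -0.90 and -0.86 relative to sham. Distal convoluted and connecting tubule markers were split, 5 higher and 5 lower, and so were podocyte markers (camera, Benjamini-Hochberg adjusted p = 0.902 and 0.869). The proximal tubule and respiratory lists depended on single vehicle libraries. Without vehicle library 2 the medians were larger, 0.83 for proximal tubule markers, 0.59 for complex I, 0.56 for complex IV, 0.43 for ATP synthase and 1.12 for the mitochondrial messenger RNAs. Without vehicle library 3 the proximal tubule list was at -0.07, complex I at 0.14, complex IV at 0.07, ATP synthase at 0.01 and the mitochondrial messenger RNAs at 0.30, with camera's Benjamini-Hochberg adjusted p = 0.902, 0.0466, 0.841, 0.911 and 0.553. Without TJ0113 library 1 the adjusted p by camera with Benjamini-Hochberg was 0.143 for proximal tubule markers, and without TJ0113 library 2 it was 0.225 for complex IV and 0.505 for ATP synthase.

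Camera called 4 more lists upward at small changes. Mitochondrial ribosomal proteins had a median of 0.12 relative to the median gene (camera with Benjamini-Hochberg adjustment, adjusted p = 8.77e-04), endothelial markers 0.21 (0.0235), cytosolic ribosomal proteins 0.14 (0.0267) and erythroid genes 0.22 (0.0493). With an estimated correlation camera's Benjamini-Hochberg adjusted p was 0.964 for the mitochondrial ribosomal, endothelial and erythroid lists and 0.973 for the cytosolic ribosomal list. As fitted, the medians of the mitochondrial and cytosolic ribosomal lists were 0.09 and 0.11, and -0.02 and 0 with equal FPKM sums. Each of the 4 lost its call when some single library was left out, the mitochondrial ribosomal list without vehicle library 3 (adjusted p = 0.788 by camera with Benjamini-Hochberg) or TJ0113 library 2 (0.0982), the endothelial list without vehicle library 2 (0.625) or TJ0113 library 2 (0.873), where its median was -0.04 in both fits. The cytosolic ribosomal list lost it without vehicle library 1 (camera with Benjamini-Hochberg, adjusted p = 0.109), vehicle library 2 (0.539), TJ0113 library 1 (0.1) or TJ0113 library 3 (0.377), and the erythroid list without vehicle library 1 (0.295), TJ0113 library 1 (0.431) or TJ0113 library 2 (0.233). Without TJ0113 library 3 the erythroid median was 0.88.

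Ferroptosis and mitophagy lists were not called. Ferroptosis drivers were lower in 18 of 22 members, with a median of -0.10 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.0972), suppressors in 15 of 25 (median -0.04; 0.778) and mitophagy genes in 20 of 32 (median -0.02; 0.411). Acsl4 was at 9.41 ± 1.46 FPKM with TJ0113 and 15.8 ± 5.56 with vehicle (SD, n = 3), a difference of -0.64 with a 95% confidence interval from -1.17 to -0.11 (limma, Benjamini-Hochberg adjusted p = 0.796). Gpx4 differed by 0.15 ± 0.24, Pink1 by 0.01 ± 0.21, Ppargc1a by -0.14 ± 0.14 and Ppara by -0.26 ± 0.25. Slc7a11, below the filter, was at 0.0983 FPKM with TJ0113. Tubular injury genes were lower in 25 of 27 members, with a median of -0.18, and extracellular matrix genes in 24 of 32, with a median of -0.08 (camera, Benjamini-Hochberg adjusted p = 0.133 and 0.516).

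Limma called 0 of 15453 genes between TJ0113 and vehicle after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.796. In 100 simulated draws in which treated and vehicle groups were equal, a mean of 632.68 genes was called (0 to 6696.925). A count of called genes can thus be large without any difference between groups. An unadjusted p under 0.05 was found for 927 genes, where chance gives 773. In a fit of only the TJ0113 and vehicle groups there were 382, fewer than chance gives (smallest Benjamini-Hochberg adjusted p = 0.513 by limma). The fit of all 9 libraries takes part of its spread from sham, whose median gene SD was 0.09, against 0.27 with vehicle and 0.19 with TJ0113. The SE, intervals and p-values given for this comparison share that limit. The TJ0113 and vehicle groups did not overlap in 7.4 percent of genes, where chance gives 10 percent. The 5 smallest p-values were those of the heat-shock gene Hspa1b (-1.14 ± 0.21), the predicted genes Gm5741 (0.57 ± 0.11) and Gm37285 (-1.08 ± 0.20), the growth factor Hbegf (-1.30 ± 0.25) and Cyp2j7 (0.62 ± 0.13), all at an adjusted p of 0.796 by limma with Benjamini-Hochberg. Voom on recovered fragments also called 0, with 902 at an unadjusted p under 0.05; limma with gene-by-gene library weights, added after the planned weights had not converged, called 468 (189 higher, 279 lower; smallest Benjamini-Hochberg adjusted p = 0.0414), and the unconverged weights called 9624. Camera called 11 of 49 lists, 9 upward and 2 downward, against 0 with an estimated correlation and 0 with fry. The 95% confidence interval of a gene's difference reached a median of 0.39 to either side; differences well above that, such as those of Fos and Atf3, did not pass the adjusted test.

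The third comparison set TJ0113-treated bIRI against sham, and addressed how much of the injury profile remained under treatment. The median of all genes was 0.26 higher than in sham. Injury, matrix and immune genes stayed far above sham, with Havcr1 at 5.84 ± 0.49 relative to the median gene (SE, n = 3), Aoc1 at 4.50 ± 0.38, Spp1, which encodes osteopontin, at 4.14 ± 0.57, and Ccl2 at 4.10 ± 0.47. Slco1a1 (-3.98 ± 0.97), Akr1c18 (-3.65 ± 0.87), Pzp (-3.32 ± 0.75), the lipoprotein lipase gene Lpl (-2.97 ± 0.57), Ctxn3 (-2.86 ± 0.45), Cyp4a12a (-2.84 ± 0.29), C1qtnf3 (-2.83 ± 0.58) and C8a (-2.80 ± 0.72) fell furthest. For these 12 genes limma's Benjamini-Hochberg adjusted p ran from 0.00287 to 0.0265.

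Of 32 extracellular matrix genes 29 rose (30 adjusted over the list alone), with Timp1 at 4.05 ± 0.54 and Col3a1 at 3.56 ± 0.48, and of 27 tubular injury genes 24 rose (26 adjusted over the list alone), with Clu at 2.01 ± 0.27 and Vcam1 at 3.71 ± 0.38. Macrophage markers rose in 17 of 19 members and cytokine genes in 21 of 26 (25 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment gave these 4 lists adjusted p = 9.23e-09, 9.62e-08, 4.13e-06 and 2.36e-07, and 0.635 for each with an estimated correlation. Proximal tubule markers fell in 9 of 31 members and 1 rose, Slc13a1 (0.76 ± 0.17), with a list median of -1.11; the bicarbonate transporter Slc4a4 was at -1.11 ± 0.19 and Lrp2 at -1.79 ± 0.34. Enzymes of the tricarboxylic acid cycle fell in 5 of 21 members (4 adjusted over the list alone), with Sucla2 at -1.35 ± 0.26 and Pdha1 at -1.34 ± 0.24. These lists had camera adjusted p = 4.56e-10 and 1.02e-08 after Benjamini-Hochberg, and 0.635 with an estimated correlation. Camera also called thick ascending limb, distal convoluted and connecting tubule, intercalated cell and principal cell markers downward. As fitted, their medians were -0.79, -0.45, -0.18 and -0.05, against -0.85 for proximal tubule markers. Those calls were lost with quantile normalization and without TJ0113 library 1 (camera, Benjamini-Hochberg adjusted p = 0.0818, 0.402, 0.221 and 0.46 in the latter). Immediate early genes rose in 7 of 14 members (8 adjusted over the list alone, 5 with median-ratio scaling and 5 with quantile normalization), with Atf3 at 1.90 ± 0.50 and Junb at 1.81 ± 0.41. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.0422, and 0.64 with an estimated correlation. This immediate early call was lost at a mean of at least 2 FPKM (camera, Benjamini-Hochberg adjusted p = 0.0579), with gene-by-gene weights (0.0505), and without sham library 1 (0.0652) or TJ0113 library 3 (0.144), among other settings. The mitochondrially encoded mRNAs had a median of -0.52 relative to the median gene, and 1 of 13 fell (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0296; 0.64 with an estimated correlation). That call was lost with median-ratio scaling (camera, Benjamini-Hochberg adjusted p = 0.178), without a filter on low values (0.0882), with the length trend removed (0.265), with quantile normalization, where the median was 0.21 (0.754), and without sham library 3 (0.0547) or TJ0113 library 1 (0.125). Complex I subunits had a median of -0.11 relative to the median gene and 0.15 as fitted (-0.10 with median-ratio scaling), with 7 of 36 higher and 1 lower (4 and 1 adjusted over the list alone; 12 and 1 with equal FPKM sums, 1 and 1 with median-ratio scaling, 5 and 1 with quantile normalization; camera, Benjamini-Hochberg adjusted p = 0.735).

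Against sham, 5384 genes changed under TJ0113, 4469 higher and 915 lower (limma, adjusted by Benjamini-Hochberg), of which 1680 changed by at least 1 as fitted; 83 percent were higher as deposited, 60.4 percent (3330 and 2186) with median-ratio scaling, 45.6 percent (2391 and 2854) with quantile normalization and 52.5 percent with the length trend removed. The count was 1272 without sham library 2, 1429 without TJ0113 library 3, 1469 without sham library 3, 2921 without sham library 1 and 3342 without TJ0113 library 1. Camera called 32 of 49 lists, 15 upward and 17 downward, against 0 with an estimated correlation and 15 with fry.

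The injury profiles of both treatment groups overlapped widely. Of the genes higher with vehicle, 3582 were also higher with TJ0113, where independent lists of these sizes would share 1399.4, and 532 of the lower genes were shared, against 49.6; 0 genes were called in opposite directions. Fold changes correlated across genes at r = 0.933, against a mean of 0.282 (-0.45 to 0.797) in unchanged groups simulated against the same sham libraries, and their covariance was 0.395 against 0.011. Part of the excess overlap may come from the shared sham libraries, which are too few to divide. The change with injury and the change with TJ0113 correlated at r = -0.231 across genes (covariance -0.036). Both use the vehicle libraries with opposite sign, so simulated groups without any change, injury included, gave -0.612 (-0.972 to 0.098) and a covariance of -0.049. In 100 simulated draws in which treated and vehicle groups were equal, the mean r was -0.15 (-0.9 to 0.645), and -0.231 lies within that range. Of the genes changed by injury, 62.3 percent differed in the opposite direction between TJ0113 and vehicle, against a mean of 57.5 percent (8.0 to 96.6) in 100 simulated draws in which treated and vehicle groups were equal. The share was 29.8 percent without vehicle library 3, 43.5 without TJ0113 library 2, 81.1 without TJ0113 library 3 and 86.2 without vehicle library 2, and 78 with equal FPKM sums. Genes are not independent replicates, so no p-value is given for these values.

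**Figure D3:**
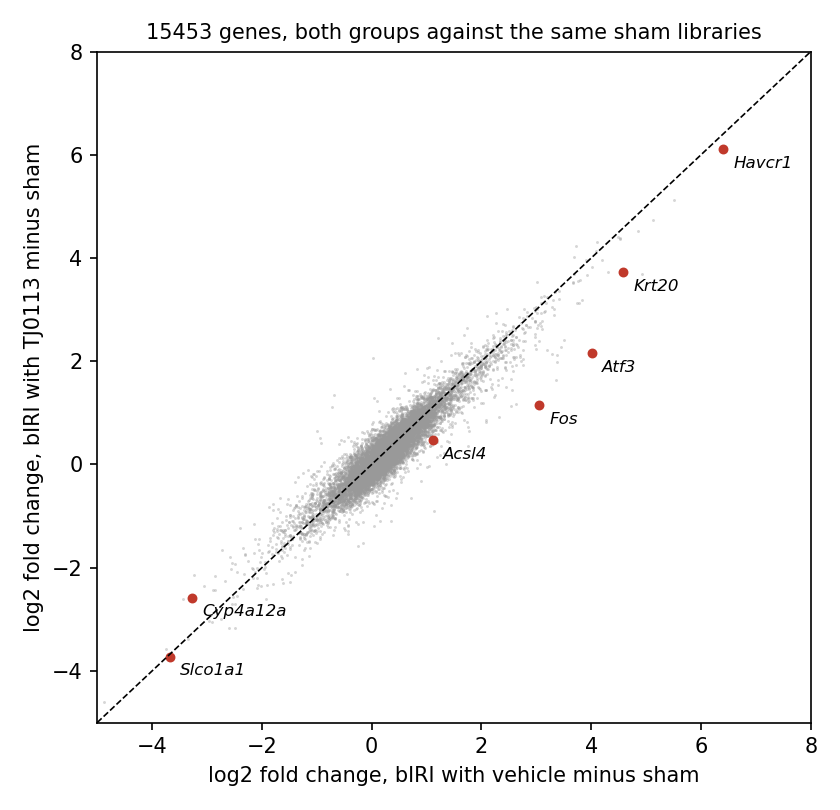
Log2 fold change from sham of each of 15453 genes, as fitted, in vehicle-treated bIRI (horizontal axis) and TJ0113-treated bIRI (vertical axis), with the line of equality dashed. Points follow the line with r = 0.933, partly because both axes share the sham libraries, and Atf3 and Fos lie below it.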

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

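The fits with equal sums without mitochondrial genes, the length trend removed, voom, gene-by-gene library weights and the proximal tubule and tubular injury covariates are tests chosen after the results were seen. The other 15 settings and the 9 fits that leave out 1 library were planned.

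Without a filter on low values 2933 genes changed between vehicle and sham and 3205 between TJ0113 and sham; with a change of at least 1 on the log2 scale they were 1783 and 1680. The planned library weights did not converge and gave 12492 genes for vehicle against sham, 9624 for TJ0113 against vehicle and 10777 for TJ0113 against sham; gene-by-gene weights gave 9737, 468 and 9359. Both put low weight on vehicle library 2 (0.11 and 0.18) and vehicle library 3 (0.16 and 0.28) against vehicle library 1 (35.09 and 2.14), so the vehicle group then rests mostly on 1 library. The replicate number as a block gave 6394, 0 and 6062. Between TJ0113 and vehicle its smallest Benjamini-Hochberg adjusted p by limma was 0.353, against 0.796 without the block.

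Camera called 19 lists between TJ0113 and sham at a mean of at least 2 FPKM, 21 with quantile normalization, 21 with the length trend removed and 20 with the proximal tubule covariate, and fry called 15. Between TJ0113 and vehicle the count was 7 with the length trend removed, 17 with the proximal tubule covariate and 0 with fry. With an estimated correlation camera called 0 lists in each of the 3 comparisons. Limma with the proximal tubule covariate called 19 genes between vehicle and sham, 0 between TJ0113 and vehicle (2078 at an unadjusted p under 0.05) and 325 between TJ0113 and sham. With the tubular injury covariate limma called 0 genes in each of the 3 comparisons (2014, 1953 and 2660 at an unadjusted p under 0.05), and camera 27, 16 and 23 lists. Relative to the sham mean, the injury list ran from -0.09 to 0.09 in sham and from 1.7 to 3.24 in injured libraries. The proximal tubule list ran from -0.1 to 0.13 and from -1.72 to -0.49. Both covariates nearly repeat the split of sham from injury, so the loss of calls against sham was largely built in.

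Some directions turned. With quantile normalization the median of complex IV subunits between vehicle and sham was 0.04 and that of the mitochondrially encoded messenger RNAs between TJ0113 and sham was 0.21. With the unconverged weights endothelial markers were at -0.14 between TJ0113 and vehicle, and at -0.04 without vehicle replicate 2 or TJ0113 replicate 2. Without a filter mitochondrial ribosomal proteins were at 0.04 between vehicle and sham, against -0.22. Without vehicle replicate 3 the proximal tubule list between TJ0113 and vehicle had a median of -0.07 and the ATP synthase list one of 0.01, with camera's direction turned; over the leave-one-out fits these lists ran from -0.07 to 0.83 and from 0.01 to 0.43. Camera works on test statistics and not on medians, which is why a median above 0 can go with a downward direction.

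Over the fits that left out 1 library, genes changed between vehicle and sham ran from 862 to 8789, between TJ0113 and sham from 1272 to 7313, and between TJ0113 and vehicle stayed at 0 in all 9 by limma, with up to 3702 at an unadjusted p under 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.0585 without vehicle replicate 2. Camera called 11 to 26 lists between TJ0113 and vehicle. The correlation between the change with injury and the change with TJ0113 ran from -0.611 to 0.154; it was 0.154 without vehicle replicate 3 and 0.0932 without TJ0113 replicate 2.

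For single genes reported between TJ0113 and vehicle, 1277 of 1340 values over all settings fell on the same side of the threshold and 63 passed it. All 63 came from library weights, 44 from the unconverged and 19 from the gene-by-gene weights. Between vehicle and sham 2935 of 3331 values stayed on the same side and 267 lost their call. Between TJ0113 and sham 2953 of 3255 stayed and 214 lost it. For lists the same held for 225 of 264 values between TJ0113 and vehicle, 734 of 791 between vehicle and sham and 686 of 767 between TJ0113 and sham. Beyond the settings named, the cause of these shifts was not tested.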

Other observations

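The heat-shock and glucocorticoid lists, the 2 covariate fits, the length trend fit and equal sums without mitochondrial genes in this part are tests chosen after the result was seen.

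Several genes outside the named groups stood out after injury, given here relative to the median gene for vehicle against sham (SE, n = 3). The NRF2 targets Cbr3 (2.14 ± 0.19) and Ephx1 (1.27 ± 0.16), the ferroxidase Cp (2.85 ± 0.44) and the heat-shock protein gene Hspb1 (3.63 ± 0.46) rose, with limma's Benjamini-Hochberg adjusted p = 0.00149, 0.00277, 0.00687 and 0.00398. The clock genes Cry1 (1.32 ± 0.28), Nfil3 (1.43 ± 0.30) and Per1 (1.46 ± 0.36) rose and Nr1d1 (-1.22 ± 0.30) fell, with limma's Benjamini-Hochberg adjusted p = 0.00878, 0.00907, 0.0116 and 0.0412. The hour of sacrifice is not given, so for clock genes injury cannot be told apart from the time of sampling. The sterol pathway gene Idi1 fell, at -1.69 ± 0.35 (limma, Benjamini-Hochberg adjusted p = 0.0185), in a cholesterol list of which 5 of 20 genes rose and 4 fell. The lists of NRF2 targets, iron handling, clock and cholesterol genes were not called between vehicle and sham (camera, Benjamini-Hochberg adjusted p = 0.108, 0.86, 0.86 and 0.0559), while fry, which does not compare with other genes, called the first 3 upward (limma, Benjamini-Hochberg adjusted p = 0.00205, 0.00205 and 0.0302). Adipose genes followed single libraries, with a list mean of 2.40 in sham library 2 against -1.18 and -1.21 in sham libraries 1 and 3, and 0.78 and 0.98 in vehicle libraries 1 and 3 against -1.30 in vehicle library 2. All 9 were lower with TJ0113 than with vehicle, by a median of -0.78 relative to the median gene (camera, Benjamini-Hochberg adjusted p = 0.17), a shift that runs beside that comparison.

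Complex I subunits were higher with TJ0113 than with vehicle in 33 of 36 genes, by a median of 0.34 relative to the median gene, a camera call that is lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.964) and with fry (0.823). A gene length trend between libraries is argued against as the whole source, since 0.25 was left after its removal (camera with Benjamini-Hochberg adjustment, adjusted p = 8.79e-06). Without vehicle library 3 the median was 0.14 and camera's Benjamini-Hochberg adjusted p 0.0466, the highest of 6 such fits (lowest 1.95e-19 without vehicle library 2, where the median was 0.59), and with the proximal tubule level as a covariate 0.16 was left, at an adjusted p of 0.0233. These p-values pass the bound written beforehand for ruling out a single library and a larger share of proximal tubule RNA, but that bound looked at p alone; each step took away more of the 0.34 than it left, and a rule on size, set after the values were seen, leaves both open. A compound effect on these transcripts therefore cannot be told apart here from the state of single vehicle libraries or from tubule content.

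Immediate early genes were lower with TJ0113 than with vehicle in all 14 members, by a median of -0.94 relative to the median gene, a camera call that is also lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.964) and with fry (0.817). A single library is argued against as the source of this median, which stayed between -1.11 and -0.77 over 6 leave-one-out fits. Camera's Benjamini-Hochberg adjusted p ran there from 3.43e-15 to 5.65e-06, the highest without vehicle library 2. With the level of the tubular injury list as a covariate, -0.86 was left (camera with Benjamini-Hochberg, adjusted p = 4.45e-10). That list differed little between the groups, at 2.59 ± 0.73 with vehicle and 2.32 ± 0.55 with TJ0113 relative to sham (SD, n = 3). The covariate could therefore remove little. The fit argues only against the difference in this list as the whole source, and leaves open milder injury that the list does not show. These p-values use the preset correlation and do not measure the spread between mice. The lowest vehicle library had a list mean of 1.64 relative to sham, and the highest TJ0113 library 1.61. A broader stress response that differed between the groups may be a source: added lists of heat-shock genes (13 of 17 lower, median -0.24 as fitted) and glucocorticoid-responsive genes (10 of 12 lower, median -0.50) had camera p = 1.38e-04 and 2.97e-04, not adjusted, and 0.0811 and 0.034 with an estimated correlation. Both lists were written after Hspa1b, Dnajb1, Fkbp5 and Sgk1 had been seen among the top genes and leave these 4 out, but the responses were picked for them; as first written they also held members of the fixed lists and the unadjusted camera results were then 8.39e-04 and 3.88e-04. Whether such a difference would come from the compound or from handling before tissue was taken was not tested, and the order and hour of sacrifice are not given in the sources used here.

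Of the genes that changed between vehicle and sham 85.3 percent were higher in the values as deposited. With equal sums the share was 91 percent, and with equal sums without mitochondrial genes 83.7 percent, which argues against the mitochondrial share alone as the source. With median-ratio scaling the share was 58.3 percent, which passes the bound written beforehand for ruling out the library total as the source, and with quantile normalization it was 46.8 percent. That bound was wrong, because both scalings centre the bulk of genes and so fix much of the outcome, and the rule that looks at quantile scaling too was set after the values were seen. Without an outside standard, a general rise of transcripts after injury cannot be told apart from a shift in the library total.

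Each comparison of 3 with 3 libraries has 10 splits of its 6 samples, too few for a share under 0.05. Between vehicle and sham 1 of 10 splits, the real one, gave as many as 5676 genes, and the highest other gave 0 (limma, with 7848 at an unadjusted p under 0.05 in the real split). Between TJ0113 and sham 1 of 10 gave as many as 5384, and the highest other gave 0 (limma). In both comparisons every other split mixed sham with injured libraries, which puts the difference between them into the spread. Few or no calls were thus likely in those splits, and they add nothing on the cause. Between TJ0113 and vehicle all 10 of 10 gave at least the 0 of the real split by limma (927 at an unadjusted p under 0.05; voom 0, gene-by-gene weights 468), and the highest other gave 1940. That split sets vehicle libraries 1 and 3 and TJ0113 library 3 against vehicle library 2 and TJ0113 libraries 1 and 2, and points to a structure of the samples: these first 3 also have the highest values of the first principal component (30.8, 70.6 and 51.1).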
